A study of Mus musculus with 12 samples.

How the data were processed

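Gene expression was measured by RNA sequencing in 12 livers without tumour, 3 male mice in each of 4 groups set by strain (LiK, LiKM) and diet (normal, 0.06% ACR), with libraries from a stranded poly(A) mRNA kit, per the labels' protocols. Groups and replicate numbers were taken from the sample titles, which name separate mice. The deposited table holds expected counts, a value for each gene symbol and library that need not be whole. Of its values above 0, 18.9% are not whole numbers (tolerance 1e-09), as arises where reads that map to several genes are shared among them. The submitters' processing notes name featureCounts 2.0.0 and the genome build mm10. The aligner, the gene annotation, the options for shared reads and the strand setting are not given in the sources used here. Genes that overlap on opposite strands, or that have near-identical copies, are therefore not separated with certainty, and named genes with values that are not whole in nearly all libraries are called uncertain. All 12 value columns matched a title, and 0 were left unmatched.

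The table lists 24421 genes, of which 5382 have a value of 0 in all libraries. Totals ran from 10124813 to 18647156 per library. No pair of libraries within a group agreed within sampling noise (chi-square per degree of freedom 15.7 to 65.1, Spearman correlation across genes 0.964 to 0.99), so none was treated as deposited more than once. Expected counts were rounded to whole numbers. Genes with too few counts were left out with edgeR's filterByExpr by group, which kept 13880 genes, and libraries were scaled with TMM factors (0.83 to 1.243). Mean factors were 0.88 in LiK on the normal diet, 0.96 in LiK on ACR, 1.15 in LiKM on the normal diet and 1.04 in LiKM on ACR. CPM values use these factors, and log2 CPM values have a prior count of 2. Positions come from the annotation of mm10.

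The main test was edgeR's quasi-likelihood test (glmQLFit with robust estimation, glmQLFTest) on all 12 libraries with 1 coefficient per group, so that all comparisons share 1 estimate of the spread. The common biological coefficient of variation was 0.203 and the prior degrees of freedom 3.96. The 5 comparisons were LiKM against LiK on each diet, ACR against normal diet in each strain, and the difference of the diet effects. P-values were adjusted by the Benjamini-Hochberg method over all genes of a comparison, with a threshold of 0.05, and "changed", "rose" and "fell" refer to this threshold unless adjusted over the list alone. Reported adjusted p-values of genes are from edgeR. Fold changes of genes with few counts in a group depend on the small count that the fit adds.

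For gene groups, 33 lists were tested with camera (limma) on voom log2 CPM of the same genes and design, with a preset correlation between genes of 0.01, again with an estimated correlation, and with fry, which asks whether a list's genes move on balance in 1 direction without comparing them with other genes. P-values were adjusted over the 165 tests of 33 lists in 5 comparisons. The lists were p53 targets, secreted factors of senescent cells, YAP and TEAD targets, progenitor and biliary markers, hepatocyte, stellate, extracellular matrix, endothelial, macrophage, T and NK cell, B and plasma cell, neutrophil, red cell precursor and pancreatic acinar markers, retinoid response, PPAR alpha, LXR, FXR and CAR and PXR targets, pericentral and periportal genes, cholesterol synthesis, fatty acid synthesis, bile acid and cell cycle genes, ERK targets, liver tumour markers, acute phase, interferon, immediate early, clock, integrated stress and NRF2 genes. Genes occur in more than 1 list in places, so list results are not independent.

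The groups, comparisons, tests, gene lists, alternatives and the rule for naming genes were fixed before the data were examined. By that rule the text names, in every comparison, Mdm2, Trp53, Cdkn1a, Ctgf, Cyp26a1, Rarb and Mycn. It names the 6 genes with the largest rise and the 6 with the largest fall among those past the threshold with a mean of at least 5 CPM in the higher group and no overlap between the groups' libraries, leaving out predicted genes (2072, 981 and 24 genes were eligible for LiKM against LiK on the normal diet, LiKM against LiK on ACR, and diet in LiK). It names up to 3 members of smallest p from each list with a member past the threshold, limited to the 10 lists with most such members. Where under 10 genes passed all were named, and where none passed the 3 of smallest p. A few genes that the rule picks are not reported here and were not replaced. Other members of the lists are given as examples and were chosen after their values were seen.

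Same-numbered mice were checked for pairing by the correlation, across genes, of their deviations from the group means. Between LiKM mice on the normal diet and on ACR it was 0.37, 0.22 and 0.48 for numbers 1, 2 and 3. For other numbers the highest values were 0.07, 0.05 and -0.22. No label says what a number shares, so the pairing of these groups is assumed from the libraries that the block tests. Elsewhere same-numbered mice correlated between -0.1 and 0.08, and the numbers were taken as names.

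On counts simulated from the means and library sizes of these samples over 13880 genes, the test recovered 6%, 54%, 84% and 92% of genes changed 1.5-, 2-, 4- and 8-fold (50 genes each) for LiKM against LiK on the normal diet, 8%, 52%, 92% and 94% on ACR, 10%, 48%, 86% and 100% for the diet in LiKM and 14%, 66%, 90% and 100% for the diet in LiK. There camera called a raised biliary list (normal diet) and 0 of 32 others, leaving correlated genes untested.

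Further fits fixed in advance used median-of-ratios size factors, no filter on low counts, a stricter filter (at least 1 CPM in 3 libraries), DESeq2's Wald test, limma voom with sample weights, the replicate number as a block, the identifier prefix of the sample names as a covariate (KM in 9 libraries, MP in 3: LiK normal diet 2, LiK normal diet 3 and LiKM ACR 3), the 6 libraries of a comparison alone, and leaving out each library in turn. After the data were seen 6 were added: library size alone, a pair of clock gene components as covariates, the block within LiKM in all libraries or in the 6 LiKM libraries alone, leaving out the 3 LiKM libraries whose clock genes stood apart, and 2 classes of libraries set by hand from clock genes as a covariate. Versions were R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.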

Results

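RNA sequencing was carried out on liver tissue without tumour from male mice of the strains LiK and LiKM, killed at 4 months of age. From what is known of the study, which the labels do not spell out, LiKM mice are meant to lack Mdm2, the ubiquitin ligase that degrades p53, in hepatocytes and LiK mice are not. ACR is an acyclic retinoid studied against liver cancer. Each strain received a normal diet or, from 5 weeks of age, a diet with 0.06% ACR. This gave 4 groups of 3 mice and 12 libraries. The replicates are separate mice, as their titles state, so the errors include the spread between animals. Libraries held 10124813 (LiKM normal diet 3) to 18647156 counts (LiK normal diet 2). Albumin, the main secreted protein of hepatocytes, took 9.9 ± 1.6% of counts in LiK mice on the normal diet (mean ± SD, n = 3, as for all group levels) and 11.5 ± 0.9% on ACR. In LiKM mice it took 8.2 ± 0.1% on the normal diet and 11.3 ± 1.6% on ACR.

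The first principal component of the 12 libraries held 45.7% of the variance and parted the strains. LiK libraries lay between -55.1 and -22.6 and LiKM libraries between 21.6 and 50.9. The second component, 13.9% of the variance, followed neither strain nor diet alone. On it the 3 LiK libraries on ACR lay between -24.5 and -23.6, LiKM normal diet 3 at -29.7 and LiKM ACR 3 at -24.6. The other libraries lay between 13.8 and 31.1. Genes of the circadian clock also differed between libraries. Dbp, an output gene of the clock, stood at log2 CPM of 7.12, 7.1 and 7.09 in the LiK mice on ACR against 5.17, 4.68 and 5 on the normal diet. Within LiKM, the clock activator Npas2 stood at 3.39 and 4.19 in LiKM ACR 2 and 3 but at -2.34 in LiKM ACR 1. The clock repressor Per2 was at 5.13 in LiKM normal diet 3 and 3.12 in LiKM ACR 3, against 6.61 to 7.2 in the other LiKM libraries. The hour of tissue collection is not given in the sources used here, and every comparison below sets libraries against each other that differ in these genes.

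**Figure D1:**
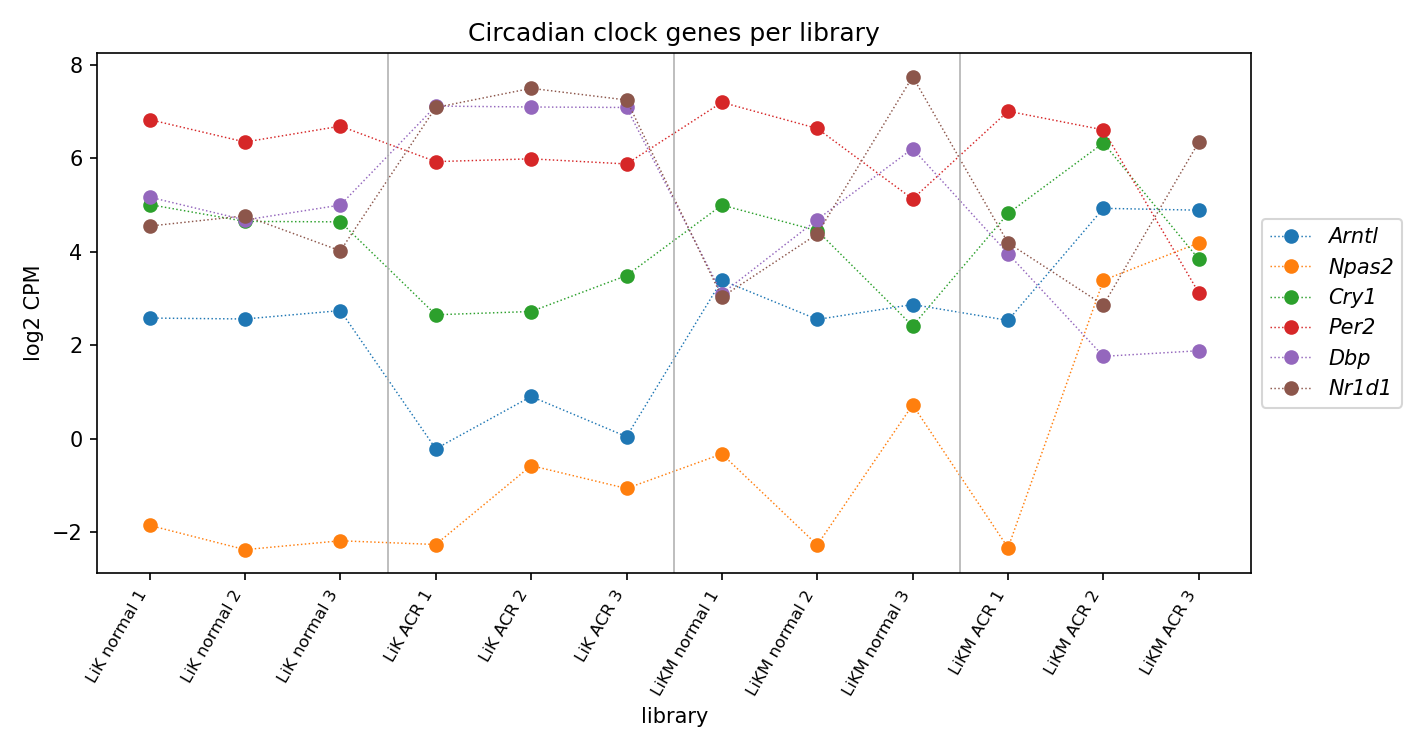
Levels of 6 clock genes (log2 CPM, y axis) in each of the 12 libraries, ordered by group along the x axis, with dotted lines that only guide the eye. Arntl lay between -0.22 and 0.9 in the 3 LiK libraries on ACR, below every other library, and at 4.93 and 4.89 in LiKM ACR 2 and LiKM ACR 3.

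The gene said to be targeted in LiKM mice, Mdm2 (mm10, chromosome 10, 117688875 to 117710758, protein coding), was counted over the whole gene, which does not check a deletion of some of its exons. Its counts were 342, 413 and 308 in the LiK mice on the normal diet and 299, 336 and 343 on ACR. In the LiKM mice they were 584, 431 and 364 on the normal diet and 511, 702 and 1101 on ACR. Scaled, these gave 24.4 ± 1.24, 22.5 ± 0.989, 31.4 ± 3.18 and 48.8 ± 17.7 CPM. Mdm2 was thus not lower in the libraries labelled LiKM, and all 6 of them lay above all 6 LiK libraries. Mdm2 is itself a target of p53, and liver holds other cells than hepatocytes. On the normal diet the strain difference did not pass the test (log2 fold change 0.37, SE 0.21, edgeR adjusted p = 0.222), though it did with library size alone as scaling (0.75, edgeR adjusted p = 0.0261). On ACR it passed (log2 1.12, SE 0.21, 2.17-fold, edgeR adjusted p = 0.0101). For Mdm2 that call ended with clock gene components as covariates (log2 -0.08, edgeR adjusted p = 0.957) and without LiKM normal diet 3, LiKM ACR 2 and LiKM ACR 3 (0.49, edgeR adjusted p = 0.0638). Cdkn1a (chromosome 17, 29090979 to 29100722), which encodes the cell cycle inhibitor p21 and is the classical p53 target, separated the strains in every mouse. It had 6.97, 3.62 and 5.95 CPM in LiK on the normal diet and 1.73, 1.66 and 1.99 on ACR. In LiKM it had 86.6, 22.9 and 15.1 CPM on the normal diet and 40.8, 113 and 54.3 on ACR.

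**Figure D2:**
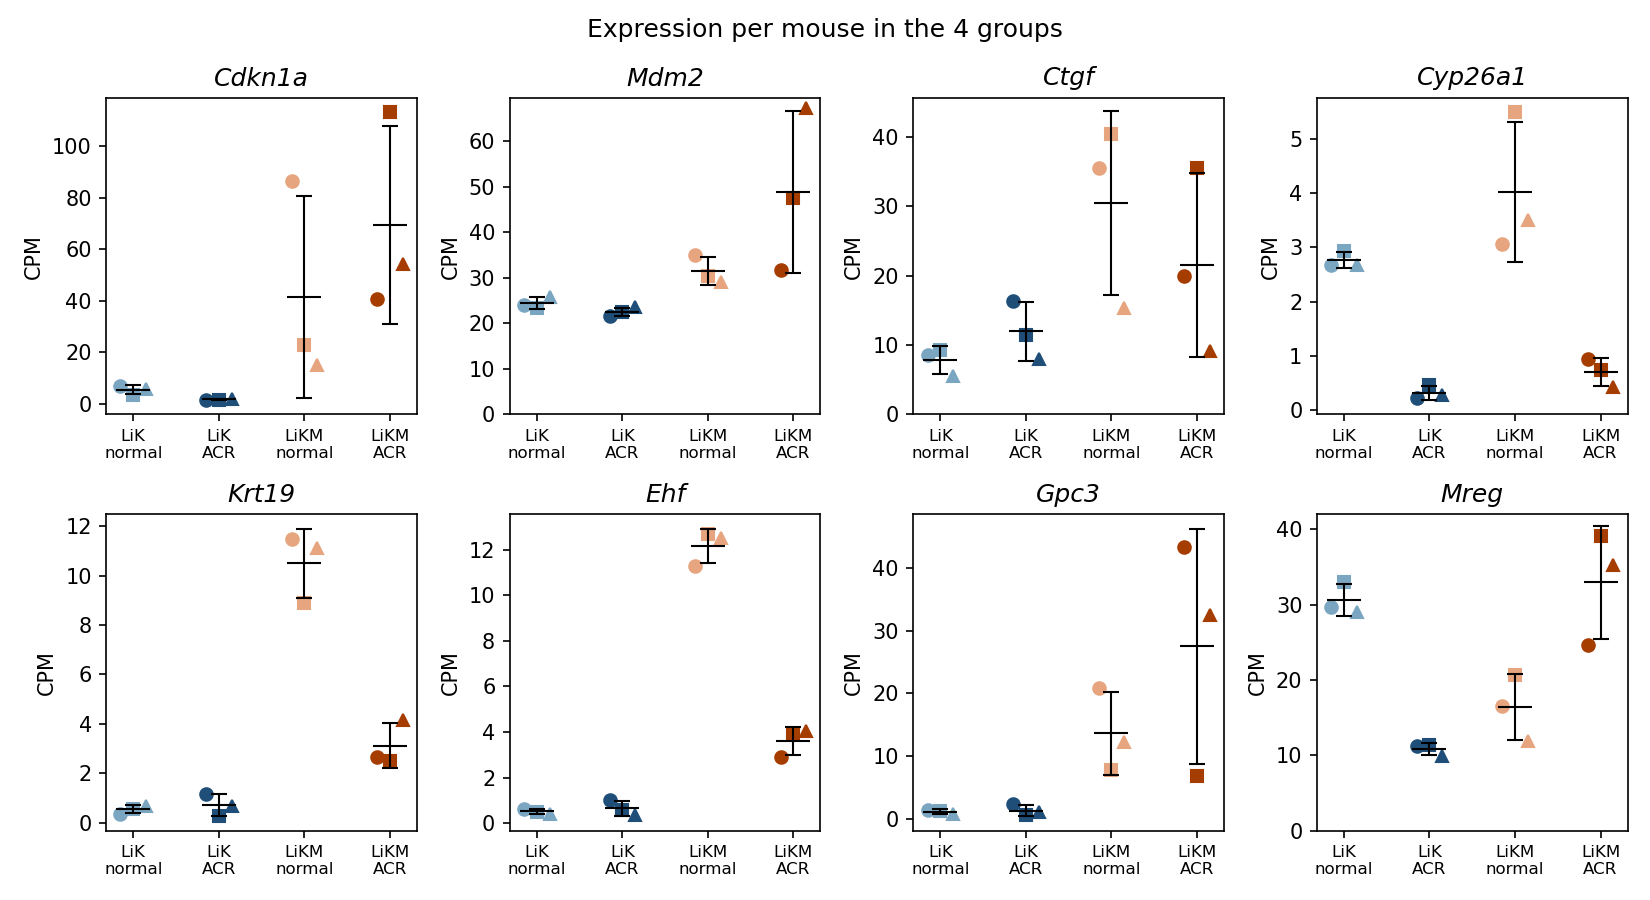
CPM per mouse (y axes from 0) of Cdkn1a, Mdm2, Ctgf, Cyp26a1, Krt19, Ehf, Gpc3 and Mreg in the 4 groups on the x axes; circles, squares and triangles are replicates 1, 2 and 3, horizontal bars are group means and whiskers SD (n = 3). Ehf stands at 12.2 ± 0.785 CPM in LiKM on the normal diet and 3.63 ± 0.611 on ACR, and the Cyp26a1 means are lower on ACR in both strains.

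The comparison of LiKM with LiK mice on the normal diet asks how the strains differ without the drug. LiKM livers expressed genes of bile duct and progenitor cells at many times the LiK level. The biliary keratin Krt19 had 0.529 ± 0.162 CPM in LiK and 10.5 ± 1.41 in LiKM, and the surface protein Cd24a 1.18 ± 0.256 and 38.8 ± 5.6. The epithelial transcription factor Ehf (chromosome 2, 103263431 to 103303275) had 0.521 ± 0.108 and 12.2 ± 0.785 CPM. Of 21 progenitor and biliary markers 18 rose, also 18 adjusted over the list alone, with a median log2 fold change of 4.25. Camera called the list (adjusted p = 1.17e-13, adjusted p = 0.106 with an estimated correlation), as did fry (adjusted p = 4.39e-05). Ehf rose 22.9-fold (log2 4.52, SE 0.3, edgeR adjusted p = 3.01e-05). Cd24a rose 32.1-fold and the chloride channel Cftr 86.8-fold (edgeR adjusted p = 9.88e-05 for both). Further members that rose were Krt7 (log2 4.4), Epcam (4.61), Spp1 (4.25), Prom1 (3.9), Cldn4 (5.02), Cldn7 (5.16) and Sox9 (2.36). Outside the list, Foxj1, a factor of ciliated cells, rose 39-fold (edgeR adjusted p = 0.000214) and Tmc5 60.1-fold (edgeR adjusted p = 0.00973). Folds of this size depend on the small count added in the fit, because these genes had few counts in LiK.

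Markers of liver tumours were also higher in this tumour-free tissue. Of 23 measured, 13 rose and 1, Gstp1 (log2 -0.81), fell, or 14 and 1 adjusted over the list alone, with a median of 1.94. Camera called them (adjusted p = 4.28e-05, adjusted p = 0.423 with an estimated correlation), as did fry (adjusted p = 0.011). The growth factor midkine, Mdk, rose 8.02-fold (edgeR adjusted p = 0.00109) and the progenitor transcription factor Sox4 12.2-fold (edgeR adjusted p = 0.000607). Tspan8, which the biliary list also holds, rose 32.2-fold (edgeR adjusted p = 0.00102). The oncofetal genes Afp and Gpc3 rose by log2 2.95 and 3.53.

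Targets of p53 rose as a group. Of 32 measured, 13 rose, also 13 adjusted over the list alone, and 26 lay above 0 with a median of 0.75. For these targets camera gave adjusted p = 0.000378 (adjusted p = 0.44 with an estimated correlation) and fry 0.0125. Cdkn1a rose 7.62-fold (log2 2.93, SE 0.66, edgeR adjusted p = 0.0123), from 5.51 ± 1.72 to 41.5 ± 39.2 CPM. Phlda3, an inhibitor of Akt, rose 7.58-fold (edgeR adjusted p = 0.00109) and Apaf1, the scaffold of the apoptosome, by log2 1.47 (edgeR adjusted p = 0.00162). Psrc1 (chromosome 3, 108383804 to 108388231) rose 32.1-fold, from 0.0845 ± 0.0849 to 3.15 ± 1.64 CPM (edgeR adjusted p = 0.000485). Eda2r (log2 2.85), Ddit4l (3.67), Ak1 (2.57), Tnfrsf10b (2) and Bax (0.78) also rose. Trp53 itself (chromosome 11, 69580348 to 69591873) went from 16.6 ± 2.66 to 24.2 ± 5.06 CPM (1.45-fold, log2 0.54, SE 0.17, edgeR adjusted p = 0.0425). That call ended without LiK normal diet 1 (edgeR adjusted p = 0.15) or 3 (0.12), LiK ACR 2 (0.0565) or 3 (0.0533), LiKM normal diet 1 (0.0667) or 3 (0.163), and LiKM ACR 1 (0.051) or 2 (0.0513).

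Genes of secreted factors, of the Hippo pathway effector YAP and of ERK signalling were higher in LiKM as well. Among secreted factors of senescent cells 10 of 24 rose, 11 adjusted over the list alone. Camera called that list (adjusted p = 0.000257, adjusted p = 0.423 with an estimated correlation). The chemokine Ccl5 rose 16.1-fold (edgeR adjusted p = 0.00281), the adhesion molecule Icam1 by log2 1.68 (edgeR adjusted p = 0.00132) and Igfbp7 from 53 ± 12.5 to 138 ± 16.8 CPM (edgeR adjusted p = 0.000954). Of 15 YAP and TEAD targets 6 rose, 7 adjusted over the list alone. For the YAP list camera gave adjusted p = 0.00111 (adjusted p = 0.44 with an estimated correlation). Ankrd1 rose 55.3-fold (log2 5.79, SE 0.57, edgeR adjusted p = 0.000153) and Tgfb2 by log2 3.9. Ctgf, the matricellular factor now called Ccn2 (chromosome 10, 24595442 to 24598683), rose 3.89-fold, from 7.8 ± 2.01 to 30.5 ± 13.3 CPM (log2 1.96, SE 0.51, edgeR adjusted p = 0.021). The Ctgf call ended without LiK normal diet 1 (edgeR adjusted p = 0.0612) or 3 (0.0752), or LiKM normal diet 1 (0.0583) or 2 (0.0574), and with the identifier prefix as a covariate (log2 1.33, edgeR adjusted p = 0.141). Of 19 feedback and target genes of ERK 8 rose, also 8 adjusted over the list alone. For the ERK list camera gave adjusted p = 0.000605 (adjusted p = 0.423 with an estimated correlation). Its members Spry1 (2.57-fold, edgeR adjusted p = 0.00138) and Spred3 (4.4-fold, edgeR adjusted p = 0.00655) are feedback inhibitors and Etv5 (log2 1.05, edgeR adjusted p = 0.00691) an ETS factor.

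Markers of immune and connective tissue cells were higher in LiKM in several lists. Among 12 T and NK cell markers 9 rose and 1, Cd4 (log2 -0.82), fell, or 10 and 1 adjusted over the list alone, with a median of 2.64. Camera called T and NK markers (adjusted p = 0.00284, adjusted p = 0.448 with an estimated correlation, 0.092 with library size alone). The cytotoxic T cell receptor chain Cd8a rose 10.7-fold (edgeR adjusted p = 0.0047) and the protease Gzmb by log2 3.05 (edgeR adjusted p = 0.008). Cd8b1, with a few counts in LiK, had 0.0423 ± 0.0373 CPM there and 0.63 ± 0.148 in LiKM. Extracellular matrix genes rose in 6 of 20, 13 adjusted over the list alone, including the basement membrane collagens Col4a1 (log2 1.46) and Col4a2 (1.35). Camera called the matrix list (adjusted p = 8.18e-05, adjusted p = 0.47 with an estimated correlation). Neutrophil markers rose in 4 of 7, 5 adjusted over the list alone, among them S100a8 (log2 2.97). Camera called neutrophil markers (adjusted p = 0.0233, adjusted p = 0.47 with an estimated correlation, 0.204 with library size alone, 0.108 with the identifier prefix). Macrophage markers rose in 5 of 19, including the monocyte receptor Ccr2 (log2 2.14). Camera called macrophage markers (adjusted p = 0.00796, adjusted p = 0.547 with an estimated correlation), but not without LiK normal diet 1 (0.111) or with library size alone (0.0889). Interferon response genes rose in 5 of 28, 3 adjusted over the list alone, and 26 lay above 0. Camera called interferon genes (adjusted p = 0.0026, adjusted p = 0.525 with an estimated correlation, 0.193 with the replicate block within LiKM). Stellate cell markers rose in 6 of 15 (camera adjusted p = 0.0674), endothelial markers in 2 of 16 (0.0872) and B and plasma cell markers in 1 of 8 (0.366), without their lists passing. Among red cell precursor markers 1 of 7, Alas2, fell (camera adjusted p = 0.289, median 0, mean -0.41), and neither of the pancreatic acinar genes measured passed (camera adjusted p = 0.436).

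Genes of hepatocyte metabolism were lower in LiKM. Hepatocyte markers fell in 6 of 20, 8 adjusted over the list alone, and 19 lay below 0. Camera called hepatocyte markers (adjusted p = 6.4e-05, adjusted p = 0.448 with an estimated correlation). Periportal genes fell in 6 of 16, 7 adjusted over the list alone, with all 16 below 0. Camera called periportal genes (adjusted p = 0.000166, adjusted p = 0.448 with an estimated correlation). Pericentral genes fell in 3 of 18. Camera called pericentral genes (adjusted p = 0.00644, adjusted p = 0.561 with an estimated correlation), but not without LiKM normal diet 3 (0.103), with the replicate block within LiKM (0.187) or with the identifier prefix (0.0623). Fatty acid synthesis genes fell in 7 of 19, 9 adjusted over the list alone, with a median of -0.76. Camera called fatty acid genes (adjusted p = 0.000166, adjusted p = 0.448 with an estimated correlation). The acetyl-CoA carboxylase Acacb was 2.05-fold lower (edgeR adjusted p = 0.00592), the acetyl-CoA synthetase Acss2 2.22-fold (edgeR adjusted p = 0.00531) and the liver pyruvate kinase Pklr 2.06-fold (edgeR adjusted p = 0.0136). PPAR alpha targets fell in 10 of 27, also 10 adjusted over the list alone. Camera called PPAR targets (adjusted p = 0.000699, adjusted p = 0.423 with an estimated correlation). The peroxisomal enzyme Ehhadh went from 202 ± 23 to 101 ± 21.3 CPM (edgeR adjusted p = 0.00145). The mitochondrial Hadha (edgeR adjusted p = 0.00449) and the factor Creb3l3 (edgeR adjusted p = 0.00815) both had log2 -0.59 and did not pass with library size alone. Bile acid synthesis and transport genes fell in 9 and rose in 2 of 20, 10 and 2 adjusted over the list alone. Camera called bile acid genes (adjusted p = 0.000169, adjusted p = 0.423 with an estimated correlation). The bile acid uptake carrier Slc10a1 went from 989 ± 122 to 502 ± 141 CPM (edgeR adjusted p = 0.00744). The basolateral exporters Abcc3 (2.02-fold, edgeR adjusted p = 0.00319) and Abcc4 (2.93-fold, edgeR adjusted p = 0.00162) rose.

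The strongest decreases among genes at 5 CPM or more concerned the sulfotransferase Sult5a1 (log2 -2.49, SE 0.58, edgeR adjusted p = 0.0117) and the phospho-lyase Etnppl (-2.44, edgeR adjusted p = 0.0349). Also among them were Ces4a (-1.92, edgeR adjusted p = 0.025), Lect1 (-1.91, edgeR adjusted p = 0.0101) and Serpina1e (-1.89, edgeR adjusted p = 0.019). Serpina1e shares reads with near-identical paralogs, and its value is uncertain. Integrated stress response genes rose in 9 of 20 and fell in 1, Shmt2 (log2 -0.55, edgeR adjusted p = 0.0182), or 10 and 1 adjusted over the list alone. Vldlr was 4.31-fold higher (edgeR adjusted p = 0.0103) and Atf3 3.54-fold (edgeR adjusted p = 0.0192). Camera called stress genes (adjusted p = 0.028, adjusted p = 0.448 with an estimated correlation), but not without LiK normal diet 3 (0.0522) or LiKM normal diet 3 (0.0908). Nor did stress genes pass with library size alone (0.418), the identifier prefix (0.0752) or without the 3 LiKM libraries whose clock genes stood apart. Immediate early and heat shock genes rose in 7 of 22 (camera adjusted p = 0.0471, adjusted p = 0.448 with an estimated correlation, 0.772 with library size alone, 0.238 with the identifier prefix). That call ended without LiK normal diet 1, LiKM normal diet 3, LiK ACR 1, 2 or 3 or LiKM ACR 2 or 3 (0.0538 to 0.0815). Camera did not call the remaining lists. Retinoid response genes had 1 of 16 higher (Tgm2, camera adjusted p = 0.497, but fry adjusted p = 0.00683 upward), LXR targets 1 of 13 lower (Scd1, 0.188), and FXR targets 2 of 10 lower (Slc10a1 and Abcb11, 0.104). CAR and PXR targets had 2 of 22 higher and 3 lower (camera adjusted p = 0.122) and cholesterol synthesis 1 of 20 lower (Stard4, 0.373). Of the cell cycle genes 0 of 30 passed (camera adjusted p = 0.87) and of the clock genes 0 of 20 (0.094). NRF2 targets had 2 of 21 higher and 1 lower (camera adjusted p = 0.373). Acute phase genes had 2 of 25 higher and 1 lower (camera adjusted p = 0.824), and their median of -0.02 and mean of 0.31 differ in sign. Cyp26a1 had a log2 fold change of 0.53 (SE 0.31, edgeR adjusted p = 0.231), Rarb of 0.38 (edgeR adjusted p = 0.22) and Mycn of 0.63 (edgeR adjusted p = 0.416).

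**Figure D3:**
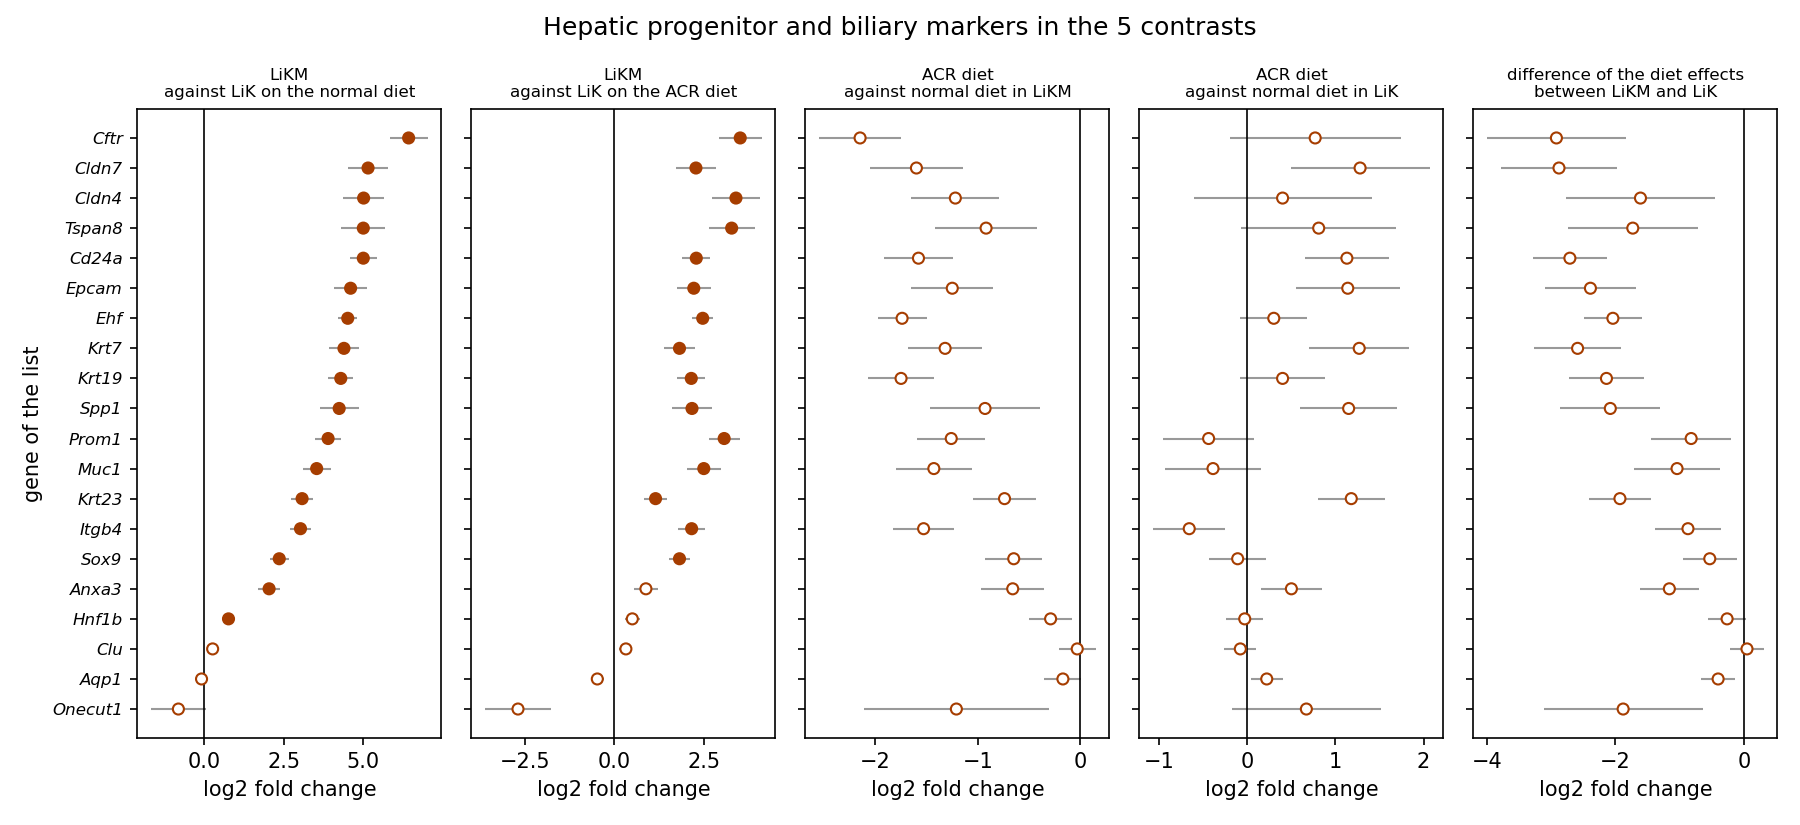
Log2 fold changes (x axes, with ranges that differ between panels) of 20 of the 21 progenitor and biliary markers in the 5 comparisons; bars are ±1 SE and filled points have an edgeR adjusted p under 0.05. Between the diets in LiKM all of them lay below 0 with none past the test.

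Of 13880 genes tested on the normal diet, 3031 differed between the strains by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 1836 higher and 1195 lower in LiKM. At least 2-fold higher were 1375 of them, and at least 2-fold lower 101. The count was 1658 without LiK normal diet 1 and 1862 without LiK normal diet 3. With library size alone as scaling 4831 genes passed, 97.6% of them higher against 60.6% with TMM factors, and the median log2 fold change of all genes moved to 0.4. Of the 42 named calls 34 passed without any single library. Without LiK normal diet 1 there ended 7 (edgeR adjusted p 0.053 to 0.15), without LiK normal diet 2 the call of Etnppl (0.106) and without LiK normal diet 3 there ended 5 (0.0568 to 0.12). Without LiKM normal diet 1 and 3 there ended 6 (edgeR adjusted p 0.0578 to 0.101) and 5 (0.0601 to 0.163). Besides Trp53 and Ctgf, these were Ces4a, Etnppl, Serpina1e, Atf3, Pklr and Shmt2. The identifier prefix as a covariate ended 3 (Ctgf, Etnppl and Serpina1e, edgeR adjusted p 0.0566 to 0.177).

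The comparison of LiKM with LiK mice on ACR asks whether the strains also differ under the drug. Biliary and progenitor markers and p53 targets were again higher in LiKM, and genes of cholesterol synthesis were lower. Cdkn1a had 1.79 ± 0.172 CPM in LiK and 69.5 ± 38.6 in LiKM, a 38.5-fold difference (log2 5.27, SE 0.75, edgeR adjusted p = 0.00533). Of 32 p53 targets 17 rose, 19 adjusted over the list alone, and 29 lay above 0. Camera gave p53 targets adjusted p = 6.69e-09 (adjusted p = 0.268 with an estimated correlation) and fry 0.00329. Phlda3 rose 9.45-fold (edgeR adjusted p = 0.00302) and Psrc1 26.8-fold (log2 4.75, SE 0.54, edgeR adjusted p = 0.00208). Of 21 biliary markers 16 rose, and adjusted over the list alone 18 rose and 2 fell, with a median of 2.17. Camera gave biliary markers adjusted p = 8.91e-10 (adjusted p = 0.169 with an estimated correlation) and fry 0.000742. Ehf rose 5.55-fold (edgeR adjusted p = 0.00253) and Prom1 8.41-fold (edgeR adjusted p = 0.0033). The retinoid response list did not pass camera (adjusted p = 0.351), while fry called it up (adjusted p = 0.005). Among the genes followed throughout, Trp53 had a log2 fold change of 0.51 (edgeR adjusted p = 0.077, 0.0469 without LiKM normal diet 3) and Ctgf of 0.85 (0.294). Cyp26a1 had 1.1 (edgeR adjusted p = 0.127), Rarb -0.24 (0.514) and Mycn 0.43 (0.63).

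The list of liver tumour markers was higher in LiKM on ACR. It had 11 of 23 members higher, 14 adjusted over the list alone, with a median of 2.01. Camera gave tumour markers adjusted p = 7.64e-06 (adjusted p = 0.423 with an estimated correlation). The oncofetal proteoglycan Gpc3 rose 21.1-fold (log2 4.4, SE 0.73, edgeR adjusted p = 0.00821), Mdk 6.25-fold (edgeR adjusted p = 0.00836) and the reductase Cbr3 10.1-fold (edgeR adjusted p = 0.0103). The imprinted growth factor Igf2 rose 21.6-fold (log2 4.43, SE 0.91, edgeR adjusted p = 0.0166), with 27.5, 1.63 and 7.07 CPM in LiKM ACR 1, 2 and 3. The imprinted noncoding RNA Meg3 (29.9-fold, edgeR adjusted p = 0.00509) and Mir675 (25.5-fold, edgeR adjusted p = 0.0379) are uncertain, the first because it shares reads with other genes and the second because it lies inside the H19 transcript.

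Genes of sterol and bile acid metabolism were lower in LiKM on ACR. All 20 cholesterol synthesis genes lay below 0, and 7 fell, 9 adjusted over the list alone. Camera gave cholesterol genes adjusted p = 2.05e-07 (adjusted p = 0.44 with an estimated correlation). The sterol carrier Stard4 stood at 180 ± 27.9 CPM in LiK and 53 ± 4.95 in LiKM (3.4-fold lower, log2 -1.77, SE 0.16, edgeR adjusted p = 0.00111). The isomerase Idi1 (1.92-fold, edgeR adjusted p = 0.0184) was also lower. Of 20 bile acid genes 5 fell and 1 rose. Camera gave bile acid genes adjusted p = 0.00182 (adjusted p = 0.448 with an estimated correlation). The export pump Abcc2 was 1.77-fold lower (edgeR adjusted p = 0.00893), the carrier Slco1a1 2.09-fold (edgeR adjusted p = 0.0131) and Amacr had log2 -0.63 (edgeR adjusted p = 0.0133). PPAR alpha targets fell in 2 and rose in 1 of 27, and adjusted over the list alone fell in 9 and rose in 2. Camera gave PPAR targets adjusted p = 0.000428 (adjusted p = 0.423 with an estimated correlation).

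Clock genes differed between the strains on ACR. The activator Arntl rose 19.3-fold (log2 4.27, SE 0.62, edgeR adjusted p = 0.00506) and the repressor Nfil3 5.08-fold (edgeR adjusted p = 0.00302). Dbp was 18.5-fold lower (log2 -4.21, SE 0.8, edgeR adjusted p = 0.0141), Bhlhe41 10.3-fold (edgeR adjusted p = 0.00298) and Ciart 8.47-fold (edgeR adjusted p = 0.0219). The list had 3 members higher and 4 lower of 20, 4 and 6 adjusted over the list alone. Camera gave clock genes adjusted p = 0.0192 (adjusted p = 0.47 with an estimated correlation), 0.213 without LiKM ACR 3, 0.179 with the replicate block within LiKM, 0.0992 with the identifier prefix and 0.193 without the 3 LiKM libraries whose clock genes stood apart. Further strong decreases were those of the replication factor Mcm10 (5.56-fold, edgeR adjusted p = 0.0102), Azin2 (5.5-fold, edgeR adjusted p = 0.00904) and Clec2h (5.29-fold, edgeR adjusted p = 0.036). Cell cycle genes lay above 0 in 29 of 30, with 2 past the test (Rrm2, Top2a) and 9 adjusted over the list alone. Camera gave cell cycle genes adjusted p = 0.000257 (adjusted p = 0.448 with an estimated correlation).

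Several lists of immune cell markers were higher in LiKM on ACR too. Macrophage markers rose in 6 of 19, 8 adjusted over the list alone (camera adjusted p = 2.17e-05, adjusted p = 0.448 with an estimated correlation). Neutrophil markers rose in 3 of 7 (camera adjusted p = 0.0126, adjusted p = 0.448 with an estimated correlation, 0.0912 with the hand-set clock classes). B and plasma cell markers rose in 1 of 8 and did not pass (median 0.15, camera adjusted p = 0.379). The lipid-associated receptor Trem2 rose 8.59-fold (edgeR adjusted p = 0.0262), Ccr2 4.3-fold (edgeR adjusted p = 0.0313) and the complement chain C1qc by log2 0.91 (edgeR adjusted p = 0.0397). T and NK cell markers rose in 4 of 12, and 7 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.00462, adjusted p = 0.448 with an estimated correlation, 0.14 with the replicate block within LiKM). Interferon response genes rose in 4 of 28, 8 adjusted over the list alone (camera adjusted p = 6.4e-05, adjusted p = 0.448 with an estimated correlation, 0.135 with that block). NRF2 targets rose in 5 of 21 (camera adjusted p = 0.00793, adjusted p = 0.453 with an estimated correlation), with Ephx1 2.32-fold (edgeR adjusted p = 0.0291) and Hmox1 1.71-fold higher (edgeR adjusted p = 0.0322). Secreted factors of senescent cells rose in 5 of 24, 9 adjusted over the list alone (camera adjusted p = 0.00986, adjusted p = 0.448 with an estimated correlation, 0.0728 without LiKM ACR 1). They included Ccl5 (5.11-fold, edgeR adjusted p = 0.023), Lif (7.21-fold, edgeR adjusted p = 0.0148) and Igfbp7 (log2 0.75, edgeR adjusted p = 0.0309). YAP targets rose in 4 of 15 (camera adjusted p = 0.0357, adjusted p = 0.47 with an estimated correlation), a call that ended without LiK ACR 3 (0.0818) or LiKM ACR 3 (0.0774) and with the block within LiKM (0.0509). The YAP list did not pass with the identifier prefix (camera adjusted p = 0.0992), library size alone (0.0506) or the hand-set clock classes (0.0566), nor without the 3 LiKM libraries whose clock genes stood apart (0.0683). Ankrd1 rose 11.4-fold (edgeR adjusted p = 0.00606), Tgfb2 5.49-fold (edgeR adjusted p = 0.0251) and Arhgef17 by log2 0.9 (edgeR adjusted p = 0.0167).

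On ACR 1359 of 13880 genes differed between the strains, 771 higher and 588 lower in LiKM, by the same edgeR test. With library size alone 77.9% of 1126 genes were higher against 56.7% with TMM factors, and the median of all genes moved to 0.14. The count was 565, 312 and 761 without LiK ACR 1, 2 and 3, and 743 without LiKM ACR 2. Of the 36 named calls 19 passed without any single library. Without LiK ACR 2 there ended 17 (edgeR adjusted p 0.0509 to 0.138), and without LiK ACR 1 and 3 there ended 11 and 10 (0.0544 to 0.123 and 0.0503 to 0.108), with Igf2 and Mir675 among them each time. Without LiKM ACR 1, 2 and 3 there ended 5, 9 and 7 (highest edgeR adjusted p 0.108, 0.102 and 0.0852), and without LiK normal diet 3 there ended 3, C1qc, Clec2h and Mir675 (highest 0.0568). C1qc also ended without LiKM normal diet 1 (edgeR adjusted p = 0.0526) and Mir675 without LiKM normal diet 2 (0.0549). With a pair of clock gene components as covariates, chosen after the data were seen, 5 genes passed, and 35 of the 36 named calls ended (edgeR adjusted p 0.214 to 0.957). Ehf went from log2 2.47 to 2.19, Gpc3 from 4.4 to 5.4, Cdkn1a from 5.27 to 1.89 and Stard4 from -1.77 to -1.03. Biliary markers had a median of 2.19 against 2.17 and their list passed (camera adjusted p = 7.81e-13), but 0 of the 21 rose against 16. The lists of cholesterol (camera adjusted p = 0.307), interferon (0.597), YAP (0.274), NRF2 (0.0827), stellate (0.677), matrix (0.33) and clock genes (0.119) then did not pass. The identifier prefix as a covariate ended 7 of the named calls (C1qc, Ccl5, Ccr2, Clec2h, Ephx1, Hmox1 and Tgfb2, edgeR adjusted p 0.0525 to 0.0778). Without LiKM normal diet 3, LiKM ACR 2 and LiKM ACR 3, whose clock genes stood apart, 6 biliary markers rose, 555 genes passed and Mdm2 did not (log2 0.49, edgeR adjusted p = 0.0638).

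The strain difference was largely of the same sign on both diets. Of the 3031 genes called on the normal diet 92.9% had the same sign on ACR, where their median log2 fold change in that direction was 0.51 against 0.96 on the normal diet. Of the 1359 called on ACR 92.6% had the same sign on the normal diet, with a median of 0.66 against 0.96 on ACR. On both diets 819 genes passed in the same direction, 527 higher and 292 lower in LiKM, where independent lists would share 152.6, and 5 passed in opposite directions. These comparisons share no library. Their fold changes correlated with r = 0.7 across 13880 genes, which are not independent replicates. The count of shared calls was 399, 195 and 473 without LiK ACR 1, 2 and 3, 526 without LiK normal diet 3, and 508 and 521 without LiKM ACR 2 and 3. With clock gene components it was 4.

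The comparison of diets in LiKM mice asks what ACR changed in them. Biliary and progenitor markers were lower on ACR as a group. All 21 lay below 0 with a median of -1.25, none passed over all genes, and 12 fell adjusted over the list alone. Camera called this list down (adjusted p = 4.82e-23, adjusted p = 0.0395 with an estimated correlation), as did fry (adjusted p = 0.000742), and it alone of the 165 list tests passed with an estimated correlation. Ehf stood at 12.2 ± 0.785 CPM on the normal diet and 3.63 ± 0.611 on ACR (log2 -1.74, SE 0.24, edgeR adjusted p = 0.0609). Krt19 stood at 10.5 ± 1.41 and 3.11 ± 0.902 CPM (log2 -1.75, edgeR adjusted p = 0.141). Cd24a stood at 38.8 ± 5.6 and 12.9 ± 3.65 CPM (-1.58, edgeR adjusted p = 0.206) and Cftr at 8.62 ± 2.7 and 1.94 ± 0.494 (-2.15, edgeR adjusted p = 0.142). Of 15 YAP targets 5 fell adjusted over the list alone (median -0.63, camera adjusted p = 1.82e-06, adjusted p = 0.319 with an estimated correlation), among them Ankrd1 (7.92 ± 1.67 and 2.44 ± 1.19 CPM). Cyp26a1 (chromosome 19, 37697738 to 37701536), the enzyme that degrades retinoic acid, had 4.02 ± 1.3 CPM on the normal diet and 0.702 ± 0.256 on ACR (5.67-fold lower, log2 -2.5, SE 0.35, edgeR adjusted p = 0.0609). The integrin chain Itga3 had 25.5 ± 2.35 and 14.2 ± 1.63 CPM (log2 -0.84, SE 0.12, edgeR adjusted p = 0.0609). Ehf, Cyp26a1 and Itga3 were the 3 genes of smallest p, and in each the 3 mice on ACR lay below the 3 on the normal diet.

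In LiKM on ACR 12 lists passed upward, none with an estimated correlation. Hepatocyte markers had 18 of 20 above 0 and a median of 0.17 (camera adjusted p = 0.000643, adjusted p = 0.448 with an estimated correlation). That list had camera adjusted p of 0.0908 without LiKM normal diet 3 and 0.0687 without LiKM ACR 1. Periportal genes had 15 of 16 above 0 and a median of 0.34 (camera adjusted p = 8.26e-05, adjusted p = 0.448 with an estimated correlation, 0.0531 without LiKM ACR 2). Macrophage and Kupffer cell markers had 18 of 19 above 0, a median of 0.59 and 4 that rose adjusted over the list alone (camera adjusted p = 4.89e-08, adjusted p = 0.44 with an estimated correlation). Among the 4 were the Kupffer cell proteins Cd5l (log2 1.12), Vsig4 (0.96) and Clec4f, at 61.3 ± 19.1 CPM on the normal diet and 109 ± 11.7 on ACR. PPAR alpha targets had 3 that rose adjusted over the list alone (camera adjusted p = 5.1e-05, adjusted p = 0.348 with an estimated correlation). Acute phase genes had a median of 0.42 (camera adjusted p = 1.96e-06, adjusted p = 0.448 with an estimated correlation). Targets of p53 (median 0.15, camera adjusted p = 0.000311, adjusted p = 0.44 with an estimated correlation) and interferon response genes (0.39, camera adjusted p = 5.63e-07, adjusted p = 0.448 with an estimated correlation) passed too. Without LiKM normal diet 3, LiKM ACR 2 and LiKM ACR 3 these had camera adjusted p of 0.974 and 0.721. Neutrophil markers had 7 of 7 above 0 (camera adjusted p = 0.0038, adjusted p = 0.448 with an estimated correlation, 0.081 without LiKM normal diet 1). B and plasma cell markers had 8 of 8 (camera adjusted p = 0.00712, adjusted p = 0.418 with an estimated correlation, 0.214 without LiKM normal diet 1, 0.0568 without LiKM ACR 3). T and NK cell markers had 9 of 12 (camera adjusted p = 0.0357, adjusted p = 0.525 with an estimated correlation, 0.534 without LiKM normal diet 1, 0.491 without LiKM ACR 3, 0.342 with the identifier prefix, 0.0789 with the block within LiKM, 0.122 with clock components). CAR and PXR targets (camera adjusted p = 0.0193, adjusted p = 0.493 with an estimated correlation) did not pass without LiKM normal diet 3 (0.557), LiKM ACR 1 (0.227) or LiKM ACR 2 (0.0748). FXR targets (camera adjusted p = 0.0486, adjusted p = 0.44 with an estimated correlation) did not pass without LiK normal diet 1, LiK ACR 1, 2 or 3, LiKM normal diet 1 or LiKM ACR 1, 2 or 3 (0.0502 to 0.456), with the identifier prefix (0.0701) or with median-of-ratios size factors (0.0527). The retinoid response list, in which Cyp26a1 fell adjusted over the list alone, had a median of 0.07 and a mean of -0.08 and did not pass (camera adjusted p = 0.824).

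No gene passed edgeR's quasi-likelihood test between the diets in LiKM, where 1005 genes had an unadjusted p under 0.05, while DESeq2 called 78 and limma voom 21. Same-numbered LiKM mice deviated together between the diets, but their pairing is assumed, as no label states it. With the replicate number as a block within LiKM 9 genes passed, 2 higher and 7 lower, including Cyp26a1 (log2 -2.49) and Ehf (-1.75), both with edgeR adjusted p = 0.0274. In the 6 LiKM libraries alone with that block 73 passed, 14 higher and 59 lower, and 11 of the 21 biliary markers fell. The planned block over all 12 libraries gave 0 genes, and both blocks within LiKM were chosen after the pairing had been checked. Without LiKM ACR 1 the count was 5, without LiK ACR 3 it was 2 and without LiK ACR 1 it was 1. Cdkn1a had a log2 fold change of 0.74 (SE 0.58, edgeR adjusted p = 0.908), Mdm2 of 0.63 (SE 0.2, edgeR adjusted p = 0.453) and Ctgf of -0.5 (0.926). Rarb had -0.68 (edgeR adjusted p = 0.44), Mycn 0.16 (0.992) and Trp53 0 (0.999). This comparison shares the LiKM normal diet mice with the strain comparison. Over 13880 genes their fold changes had r = -0.41 and covariance -0.139. In 20 simulations without effects or LiKM pairs they averaged -0.5 (-0.55 to -0.47) and -0.056. Only the observed covariance was more negative.

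In LiK mice Cyp26a1 was lower on ACR, and the number of other genes called depended on the tool and the libraries used. Cyp26a1 went from 2.77 ± 0.152 to 0.319 ± 0.131 CPM, with raw counts of 38, 52 and 32 against 3, 7 and 4 (8.43-fold lower, log2 -3.08, SE 0.39, edgeR adjusted p = 0.017). The zinc importer Slc39a4 rose from 16.2 ± 5.23 to 45.5 ± 5.67 CPM (2.81-fold, edgeR adjusted p = 0.0179) and the interleukin-1 antagonist Il1rn from 1.8 ± 0.823 to 8.12 ± 0.978 (4.56-fold, edgeR adjusted p = 0.0201). Stard4 rose from 84 ± 7.49 to 180 ± 27.9 CPM (2.15-fold, edgeR adjusted p = 0.02) and Abcc3 from 65.3 ± 14.7 to 149 ± 26.9 (2.27-fold, edgeR adjusted p = 0.0223). The lipopolysaccharide-binding protein Lbp rose 2.16-fold (edgeR adjusted p = 0.02). The fatty acid hydroxylases Cyp4a31 (4.67-fold, edgeR adjusted p = 0.017) and Cyp4a32 (2.65-fold, edgeR adjusted p = 0.02) also rose, but they share reads with near-identical paralogs and are uncertain. Dab1, a reelin pathway adaptor, rose 14-fold and Cpeb1 2.95-fold (edgeR adjusted p = 0.02 for both), and Psd4 2.79-fold (edgeR adjusted p = 0.022). The acyltransferase Agpat2 fell from 224 ± 16.7 to 104 ± 9.69 CPM (edgeR adjusted p = 0.017). Melanoregulin, Mreg (chromosome 1, 72159233 to 72212314), fell from 30.5 ± 2.15 to 10.8 ± 0.793 CPM (edgeR adjusted p = 0.0179). Tmie was 3.4-fold lower (edgeR adjusted p = 0.0352), Slc45a3 3.19-fold (edgeR adjusted p = 0.0452) and Net1 1.94-fold (edgeR adjusted p = 0.0373). The pseudogene Ces2d-ps (2.61-fold lower, edgeR adjusted p = 0.0488) shares reads with other carboxylesterase genes.

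Cholesterol synthesis genes were higher in LiK mice on ACR, with 19 of 20 above 0 and a median of 0.75. Of these 1, Stard4, passed and 11 rose adjusted over the list alone (camera adjusted p = 4.33e-12, adjusted p = 0.418 with an estimated correlation, fry adjusted p = 0.0253). Fatty acid synthesis genes had a median of -0.76, none past the test and 9 that fell adjusted over the list alone, among them Fasn (log2 -1.59). Camera called them down (adjusted p = 1.83e-05, adjusted p = 0.448 with an estimated correlation, 0.33 with clock gene components as covariates). Cell cycle genes had a median of -0.37, and 6 fell adjusted over the list alone, among them the replication genes Mcm5 (log2 -2.48) and Rrm2 (-2.5). Camera called these down (adjusted p = 0.000708, adjusted p = 0.47 with an estimated correlation, 0.785 with the identifier prefix as covariate). Biliary markers had 15 of 21 above 0 and a median of 0.5, which was -0.01 without LiK ACR 1, and did not pass (camera adjusted p = 0.24). Targets of p53 did not pass either (median -0.03, camera adjusted p = 0.824). Beside these lists moved the clock genes, of which Arntl (log2 -2.42) and Nfil3 (-1.72) fell and Bhlhe41 (1.97) rose adjusted over the list alone. The interferon response list passed upward (camera adjusted p = 0.00117, adjusted p = 0.5 with an estimated correlation), as did the macrophage list (0.0038, adjusted p = 0.525 with an estimated correlation), which did not pass without LiK normal diet 1 (0.393) or LiK ACR 3 (0.121). Interferon genes did not pass with the hand-set clock classes (camera adjusted p = 0.894). Also upward were T and NK markers (median 1.33, camera adjusted p = 0.0128, adjusted p = 0.47 with an estimated correlation, 0.0842 without LiK ACR 3). Neutrophil markers passed (median 1.69, camera adjusted p = 0.0105, adjusted p = 0.448 with an estimated correlation), but not without LiK normal diet 1 (0.0723) or LiK ACR 2 (0.0559) or with the identifier prefix (0.153). B and plasma cell markers passed (median 1.08, camera adjusted p = 0.0379, adjusted p = 0.44 with an estimated correlation), but not without LiK normal diet 2 or 3, LiK ACR 2 or 3 or LiKM ACR 3 (0.058 to 0.0905) or with the identifier prefix (0.146).

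Further lists upward in LiK on ACR were endothelial markers (camera adjusted p = 0.0152, adjusted p = 0.547 with an estimated correlation), which did not pass without LiK normal diet 1 (0.527) or LiK ACR 3 (0.176), and secreted factors of senescent cells (camera adjusted p = 0.00855, adjusted p = 0.448 with an estimated correlation, 0.0578 without LiK normal diet 1). Integrated stress genes passed (camera adjusted p = 0.0214, adjusted p = 0.448 with an estimated correlation), but not without LiK ACR 3 (0.0593) or with the identifier prefix (0.099). Acute phase genes passed (camera adjusted p = 0.0357, adjusted p = 0.645 with an estimated correlation), but not without LiK normal diet 1 or 2, LiK ACR 1 or 2, LiKM normal diet 1 or 3 or LiKM ACR 3 (0.0534 to 0.126) or with the identifier prefix (0.219). The retinoid response list did not pass camera (adjusted p = 0.497), while fry called it down (adjusted p = 0.0274), with Cyp26a1 its only member past the test. Library size alone ended the calls of secreted factors (camera adjusted p = 0.0506), T and NK markers (0.0758), B and plasma cell markers (0.121), acute phase genes (0.0771) and integrated stress genes (0.113). Clock components ended those of T and NK (camera adjusted p = 0.0957), B and plasma cell (0.461) and neutrophil markers (0.0755) and stress genes (0.409). The hand-set clock classes ended those of T and NK (camera adjusted p = 0.321), B and plasma cell markers (0.298), fatty acid synthesis (0.568) and stress genes (0.657). Leaving out the 3 LiKM libraries whose clock genes stood apart ended that of acute phase genes.

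In all 27 of 13880 genes differed between the diets in LiK, 18 higher and 9 lower on ACR, by the same edgeR test, and 1953 had an unadjusted p under 0.05. DESeq2 called 401, limma voom 677 and edgeR on the 6 LiK libraries alone 812. With library size alone 75.9% of 29 genes were higher, against 66.7% with TMM factors, and the median of all genes moved to 0.13. None of the 17 named calls held in each leave-one-out fit. No gene passed without LiK normal diet 2, LiK normal diet 3 or LiK ACR 1, where the 17 had edgeR adjusted p of 0.0737 to 0.114, 0.0758 to 0.147 and 0.0799 to 0.206. Without LiK normal diet 1, LiK ACR 2 and LiK ACR 3 there passed 9, 12 and 13 genes, and 11, 9 and 10 of the 17 ended (highest edgeR adjusted p 0.142, 0.176 and 0.146). Without LiKM normal diet 2 the calls of Ces2d-ps, Net1, Slc45a3 and Tmie ended (edgeR adjusted p 0.0617 to 0.0696). The identifier prefix as a covariate ended 13 of the 17 (edgeR adjusted p 0.0565 to 0.0678), and LiK normal diet 2 and 3 carry MP while every LiK library on ACR carries KM. With clock gene components as covariates, chosen after the data were seen, no gene passed and the 17 had edgeR adjusted p of 0.256 to 0.607. Not past the test were Cdkn1a (log2 -1.6, SE 0.76, edgeR adjusted p = 0.374, 0.0172 in the 6 LiK libraries alone), Mdm2 (-0.12, 0.825) and Ctgf (0.61, 0.615). Nor were Mycn (0.36, edgeR adjusted p = 0.79), Rarb (-0.07, 0.911) and Trp53 (0.03, 0.96).

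Whether ACR acted differently in the strains was tested as the difference of the diet effects. Mreg alone passed, and 260 genes with the replicate block within LiKM, Mreg among them (edgeR adjusted p = 0.00128). It fell from 30.5 ± 2.15 to 10.8 ± 0.793 CPM on ACR in LiK and stood at 16.4 ± 4.43 and 33 ± 7.53 CPM in LiKM, a difference of log2 2.51 (SE 0.29, edgeR adjusted p = 0.0201). The biliary list passed downward, with 20 of 21 below 0, a median difference of -1.88 and 10 lower adjusted over the list alone. Camera gave this difference adjusted p = 1.11e-07 (adjusted p = 0.258 with an estimated correlation) and fry 0.0125. For Cyp26a1 the difference was 0.57 (SE 0.53, edgeR adjusted p = 0.713), for Cdkn1a 2.34 (SE 0.96, edgeR adjusted p = 0.396) and for Mdm2 0.75 (0.364). For Ctgf it was -1.11 (edgeR adjusted p = 0.572), for Mycn -0.2 (0.938), for Rarb -0.61 (0.469) and for Trp53 -0.03 (0.974). The Mreg call ended without LiK normal diet 1, 2 or 3 (edgeR adjusted p = 0.088, 0.0873 and 0.0784), LiK ACR 1, 2 or 3 (0.0516, 0.0566 and 0.104) or LiKM ACR 2 (0.0702). For Mreg it also ended with the identifier prefix (log2 2.4, edgeR adjusted p = 0.0984), clock gene components (1.51, edgeR adjusted p = 0.964) and the hand-set clock classes (2.32, edgeR adjusted p = 0.0517). At an unadjusted p under 0.05 there were 1593 genes. With library size alone 16 passed, 6.2% of them positive, and the median of all genes moved to -0.29. Averaged over both strains, a further test added beside the 5 comparisons, ACR changed 4 genes. These were Cyp26a1 (log2 -2.79, SE 0.26, edgeR adjusted p = 0.00256), Cyp4a32 (1.35, edgeR adjusted p = 0.00478), Cyp4a31 (1.75, edgeR adjusted p = 0.00506) and Als2cl (-0.51, edgeR adjusted p = 0.0398), the last chosen after its value was seen.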

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

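The tests of explanations in this part were chosen only after the result was seen, except that of a diet response shared by the strains, while the test of the difference of the diet effects and its gene lists were fixed before. The diet effects differed between the strains by a test of the difference itself for 1 gene and 12 gene lists. Mreg fell on ACR in LiK and not in LiKM, with a difference of log2 2.51 (edgeR adjusted p = 0.0201). Lists with a lower diet effect in LiKM were biliary markers (camera adjusted p = 1.11e-07, median difference -1.88), cholesterol synthesis (camera adjusted p = 7.8e-06, -0.56), secreted factors of senescent cells (camera adjusted p = 0.0163, -0.42), endothelial markers (camera adjusted p = 0.0186, -0.26), YAP targets (camera adjusted p = 0.0212, -0.63) and ERK targets (camera adjusted p = 0.0254, -0.38). With an estimated correlation their adjusted p-values were 0.258, 0.448, 0.448, 0.561, 0.448 and 0.448. Lists with a higher diet effect in LiKM were periportal genes (camera adjusted p = 0.000114, median difference 0.56), cell cycle genes (camera adjusted p = 0.000259, 0.7), fatty acid synthesis (camera adjusted p = 0.000378, 0.67), hepatocyte markers (camera adjusted p = 0.0023, 0.36), CAR and PXR targets (camera adjusted p = 0.0168, 0.65) and p53 targets (camera adjusted p = 0.032, 0.17). With an estimated correlation theirs were 0.448, 0.448, 0.448, 0.46, 0.477 and 0.501, so none of the 12 passed. Calls also ended with the identifier prefix for p53 (camera adjusted p = 0.5), cell cycle (0.845) and ERK genes (0.159), with library size alone for secreted factors (0.195), YAP (0.0516) and ERK targets (0.205), and with the block within LiKM for p53 targets (0.0739). With clock components they ended for periportal (camera adjusted p = 0.0777), hepatocyte (0.184), CAR and PXR (0.597), secreted factor (0.273), p53 (0.259), cholesterol (0.865) and fatty acid genes (0.594). With the hand-set classes they ended for periportal (camera adjusted p = 0.283), hepatocyte (0.559), CAR and PXR (0.313), fatty acid (0.701) and ERK genes (0.123). Without the 3 LiKM libraries whose clock genes stood apart, which leaves LiKM ACR 1 alone in its group, they ended for p53, secreted factor and endothelial genes. Leaving out single libraries ended them for p53 targets without LiK ACR 2, LiKM normal diet 2, LiKM ACR 2 or LiKM ACR 3 (0.0663 to 0.166) and for secreted factors without LiK normal diet 1, LiKM normal diet 1, LiKM ACR 2 or LiKM ACR 3 (0.0505 to 0.124). They ended for YAP targets without LiK normal diet 1, LiK ACR 1 or LiKM normal diet 1 (0.054 to 0.232) and for endothelial markers without LiK normal diet 1, LiK ACR 3, LiKM normal diet 1 or LiKM ACR 3 (0.0807 to 0.274). They ended for ERK targets without LiK normal diet 2, LiK ACR 1 or LiKM normal diet 1 (0.0718 to 0.405), for CAR and PXR targets without LiKM normal diet 3 or LiKM ACR 1 (0.0842 and 0.059) and for cell cycle genes without LiKM ACR 3 (0.0568). No group has 4 mice, so no single library was tested as far from its group.

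Other divisions of the same libraries show how far the counts of genes depend on the grouping. For LiKM against LiK the true division gave 3031 genes on the normal diet and 1359 on ACR, and every other division 0, so 1 of 10 reached the true count each time. In LiK the diets gave 27 genes and the highest other division 1, again 1 of 10. With 10 divisions these are too few for a share under 0.05. In LiKM the diets gave 0 genes, a count that all 10 divisions reach whatever they give, so it tests nothing. In LiKM the division that put LiKM normal diet 1 with LiKM ACR 1 and 2 gave 133 genes, and the one that put LiKM normal diet 3 with LiKM ACR 2 and 3 gave 63, which points to a structure among these mice other than diet. The other divisions that part all 3 same-numbered pairs, as the diets do, gave 0, 1 and 0. For the difference of the diet effects, 12 of 100 regroupings gave at least the 1 gene found, with a highest of 259. Chance is therefore not excluded for the Mreg call by this test, which does not keep the same-numbered LiKM pairs together, and the highest counts group LiKM normal diet 3 with LiKM ACR 3. With the assumed pairing as a block, Mreg kept its call.

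The first pattern weighed is that clock genes differ between libraries. ACR alone does not set them in LiKM, where 18 of 20 ranged wider among 3 mice on ACR than the LiK diet means differ. In LiK that is not excluded. Different clock phases remain likely, since in 10 of 12 libraries the deviations of 14 clock genes followed their textbook peak hours better than 95% of 1000 reassigned hours. LiK normal diet 2 and 3 did not. The hour of collection could settle this, and is not given.

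The second pattern is the lower level of biliary markers on ACR in LiKM. Equal dilution of other cells by hepatocytes is argued against as the whole cause. Quartiles were -1.58 to -0.74 for biliary but -0.21 to 0.05 for stellate and -0.26 to 0.11 for endothelial markers. Macrophage markers (0.39 to 0.85) may rise alone. Hepatocyte markers (median 0.17) and periportal genes (0.34) were higher, so partial dilution stays open. Clock phase as the whole cause is argued against: the median was -1.12 with clock components and -1.25 without. Fewer biliary cells or lower expression per cell may each give this result, and no test made here parts them.

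The third pattern is the set of genes called between the diets in LiK. Clock phase may not be the whole cause for the lower Cyp26a1 and the higher Cyp4a31 and Cyp4a32, the LiK calls that also passed in the paired LiKM fit, since in LiKM with clock gene components as covariates their log2 fold changes less 2 SE stayed at -1.26, 0.6 and 0.55. With these components the LiK calls ended, Cyp26a1 going from -3.08 (SE 0.39) to -3.33 (SE 0.53, edgeR adjusted p = 0.256), Cyp4a31 from 2.22 (SE 0.28) to 2.24 (SE 0.46, edgeR adjusted p = 0.493) and Cyp4a32 from 1.41 (SE 0.2) to 1.55 (SE 0.33, edgeR adjusted p = 0.493), and why they ended was not tested. In LiKM Cyp26a1 went from -2.5 (SE 0.35) to -2.11 (SE 0.42, edgeR adjusted p = 0.641), Cyp4a31 from 1.27 (SE 0.27) to 1.32 (SE 0.36, edgeR adjusted p = 0.704) and Cyp4a32 from 1.29 (SE 0.2) to 1.1 (SE 0.27, edgeR adjusted p = 0.673). For the remaining genes diet and clock phase cannot be told apart either, as the components of the 2 LiK diet groups do not overlap. That 0 genes then passed does not decide it.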

How the results depend on the processing

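Of the tests in this part, 6 alternatives were chosen only after the data were seen: library size alone, 2 clock gene components as covariates, the block within LiKM, that block in the 6 LiKM libraries alone, leaving out LiKM normal diet 3, LiKM ACR 2 and LiKM ACR 3, and 2 classes of libraries set by hand from clock genes. Median-of-ratios factors and the stricter filter kept every count of genes within 1.5 times. For all changes below the cause was not tested, except that fits with fewer libraries have fewer degrees of freedom. With 3 mice per group and 10124813 counts or more, 6% to 14% of genes changed 1.5-fold were recovered in simulation.

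Counts of genes moved as follows. For LiKM against LiK on the normal diet, library size alone gave 4831. On ACR, DESeq2 gave 2150, limma voom 2180, clock components 5, leaving out the 3 LiKM libraries 555 and the hand-set classes 2111. For the diet in LiKM, DESeq2 gave 78, limma voom 21, clock components 1, leaving out the 3 libraries 1 and the classes 7. For the diet in LiK, DESeq2 gave 401, limma voom 677, the prefix 16, the 6 libraries alone 812, clock components 0, leaving out the 3 libraries 624 and the classes 1. For the difference of the diet effects, no filter gave 2, DESeq2 160, limma voom 34, the prefix 0, library size alone 16, clock components 0, leaving out the 3 libraries 15 and the classes 4. Strain calls shared by both diets were 1250 with DESeq2, 1231 with limma voom, 445 with the prefix, 475 with 6 libraries per comparison, 4 with clock components and 296 without the 3 libraries.

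The replicate number as a block over all libraries gave 3006 and 1312 genes between the strains on the normal diet and ACR, 0 and 36 between the diets in LiKM and LiK, and 2 for the difference of the diet effects. It ended the calls of Ces2d-ps, Net1 and Tmie between the diets in LiK and of Clec2h between the strains on ACR, where same-numbered mice did not deviate together. The biliary list in LiKM kept its call with this block (camera adjusted p = 2.09e-24). The block within LiKM gave 9 genes between the diets in LiKM, and 73 in the 6 LiKM libraries alone. It gave 701 genes between the diets in LiK and 260 for the difference of the diet effects. It ended 5 named calls between the strains on the normal diet and 9 on ACR. Trp53 between the diets in LiKM stood at log2 0 with the block over all libraries, 0.01 with the block within LiKM and 0.03 in the 6 LiKM libraries with the block. In the paired diet comparison in LiKM, T and NK markers lost their call with the block within LiKM (camera adjusted p = 0.0789), and the block ended no other list call there.

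Camera called 74 of the 165 list tests, 1 with an estimated correlation, and fry 25. With an estimated correlation p53 targets had camera adjusted p of 0.44 on the normal diet and 0.268 on ACR between the strains. Biliary markers had 0.106 and 0.169, and 0.258 for the difference of the diet effects. Lists turned direction with clock components for stellate markers between the strains on ACR (camera adjusted p = 0.677), and in the difference of the diet effects for p53 targets (0.259), cholesterol (0.865) and fatty acid synthesis (0.594). With the hand-set classes hepatocyte markers (camera adjusted p = 0.559) and CAR and PXR targets (0.313) turned in that difference. Of 91 list tests not called, no filter called 11, the prefix 7, the block over all libraries 4, fry 4, library size alone 16, clock components 16, the block within LiKM 9, leaving out the 3 LiKM libraries 16 and the classes 26. Leaving out single libraries called 2 to 12 of them. Called in the direction opposite to that reported were 3 with clock components, 3 without the 3 LiKM libraries, 3 with the classes, 1 with the block within LiKM and 2 without LiKM normal diet 3.

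Of the named genes that turned sign, Dbp (log2 0.31), Hmox1 (-0.19) and Mdm2 (-0.08) had been called, between the strains on ACR, and turned with clock components. The others had not passed. With clock components Ctgf (-0.16), Mycn (-0.93) and Rarb (0.28) turned between the strains on ACR, Cdkn1a (-0.26), Mycn (-0.09) and Trp53 (0.03) between the diets in LiKM, and Cdkn1a (0.46), Mdm2 (0.31) and Trp53 (-0.19) in LiK. In the difference of the diet effects Cdkn1a (-0.72), Mdm2 (-0.23) and Trp53 (0.22) did. With the hand-set classes Ctgf (-0.28) and Mycn (-0.75) turned on ACR, Trp53 in LiKM (0.01), Trp53 in LiK (-0.32) and Trp53 in the difference (0.33). Without the 3 LiKM libraries Cdkn1a (-0.41), Mdm2 (-0.03) and Trp53 (0.13) turned in LiKM and Trp53 in the difference (0.1). With library size alone Mdm2 (0.01) and Rarb (0.06) turned in LiK. With the prefix Ctgf (-0.03), Mdm2 (0.14), Mycn (-0.07) and Rarb (0.02) turned in LiK and Mycn in the difference (0.35). With limma voom Trp53 turned in LiKM (0.12) and Mycn (0.03) and Trp53 (0.05) in the difference. Trp53 in LiKM was 0.01 with median-of-ratios factors and DESeq2 and 0.02 in the 6 libraries alone.

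Leaving out each library in turn gave 1658 to 3384 genes between the strains on the normal diet, 312 to 1695 on ACR and 195 to 873 on both. Between the diets it gave 0 to 5 in LiKM, 0 to 108 in LiK and 0 to 20 for the difference. List calls ranged from 64 to 80. Camera adjusted p of p53 targets ranged from 0.000164 to 0.00107 on the normal diet and from 1.54e-10 to 9.88e-08 on ACR. For biliary markers it ranged from 5.12e-15 to 3.95e-12, from 3.71e-12 to 1.76e-08, from 2.92e-25 to 6.34e-16 between the diets in LiKM and from 3.94e-09 to 1.57e-05 for the difference. Sign changes occurred for genes not called: Mycn (-0.12 to 0.98) between the strains on the normal diet, Mycn (-0.2 to 0.92) and Trp53 (-0.13 to 0.18) between the diets in LiKM, Rarb (-0.24 to 0.03) and Trp53 (-0.07 to 0.17) in LiK, and Mycn (-0.56 to 0.54) and Trp53 (-0.17 to 0.15) in the difference.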

Other observations

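Levels of several genes varied between the LiKM mice on ACR. H19 stood at 469, 81.9 and 36.4 CPM in LiKM ACR 1, 2 and 3, against 58.7, 31.3 and 24.3 CPM in the LiKM mice on the normal diet. Afp stood at 180, 17.9 and 71.6 CPM against 63.2, 15.6 and 25.2, and Gpc3 at 43.3, 6.78 and 32.5 against 20.8, 7.82 and 12.3.

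In the 6 LiKM libraries alone with the replicate number as a block, a fit chosen only after the data were seen, further genes differed between the diets. The receptor kinases Ephb2 (log2 -2.86, SE 0.36, edgeR adjusted p = 0.024) and Ntrk2 (-2.22, edgeR adjusted p = 0.0127) fell. So did the polycystic disease gene Pkhd1 (-1.16, edgeR adjusted p = 0.0127) and the secretin receptor Sctr (-2.64, edgeR adjusted p = 0.041). Etnppl rose (2.19, SE 0.17, edgeR adjusted p = 0.00899), as did the retinol dehydrogenase Rdh1 (1.06, edgeR adjusted p = 0.0282). These genes were chosen after their values were seen.

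A hypothesis written before its test held that the diet changes the same genes in both strains. Of the 27 genes called between the diets in LiK, 11 had the same sign in LiKM, where their median log2 fold change in the LiK direction was -0.07 against 1.26 in LiK. Of 20 assignments of the LiKM mice to the diets 14 gave at least as many, with a highest of 20, and over all genes r was 0.04. The test was negative for these genes as a set. In the paired LiKM fit above 3 of the 27 passed in the same direction and 0 in the other: Cyp26a1 (-2.46, edgeR adjusted p = 0.0386), Cyp4a31 and Cyp4a32 (both 1.3, edgeR adjusted p = 0.0127).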
